A study of Mus musculus with 6 samples.

How the data were processed

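Whole testes of mice aged 35 days were the source of polyadenylated RNA, and stranded libraries were made with the TruSeq kit, per the labels' protocols. Groups were taken from the library titles, with 3 control libraries (floxed Ptbp1, no Cre) and 3 Ptbp1_cKO libraries (floxed Ptbp1 with Amh-Cre). The submitters' processing notes name bcl2fastq 2.20, Trimmomatic 0.38, STAR 2.6.1d, Cufflinks and Cuffdiff and the genome build mm10, with no role, order or setting; the Cuffdiff version, its library normalisation and the annotation release are not given in the sources used here.

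The single file used is the authors' deposited table of Cuffdiff's gene test. It holds for each gene the FPKM of each group, which the authors obtained by combining the 3 libraries of a group. The table also holds the deposited log2 fold change of Ptbp1_cKO over control, a test statistic that is a signed score per the file headers, and the deposited p-value and q-value. No value per library was used, so no replicate could be left out, blocked or reassigned, and no SD was computed. Of 55331 genes, 22048 had test status OK, 33263 were marked as not tested, 18 as having too much data (HIDATA) and 2 as failed. The deposited log2 fold changes equalled the log2 ratio of both FPKM values within 1.37e-05 for the 22020 tested genes above 0 in both groups, and Benjamini-Hochberg adjustment of the deposited p over tested genes gave the deposited q within 5.20e-07. A fold against a group listed at 0 was not computed, since an exact 0 in this table can be a failed estimate: Prm2, among the most abundant transcripts of spermatids, was listed at 0 in both groups with status HIDATA.

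The main test was Cuffdiff's as deposited, at q under 0.05 among genes with status OK, fixed before the data were examined together with 12 cell type lists and 7 process lists. For each list the tested members past the threshold were counted, over all genes and with Benjamini-Hochberg adjustment over the list alone. The median difference of log2(FPKM + 1), Ptbp1_cKO minus control, was taken over members with an FPKM of at least 0.1 in a group; this scale understates the change of low genes. The percentile of each median was found among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description without a p-value. The list symbols Pvrl2, Pvrl3, Mllt4 and Hbb-b1 matched no row, and Nectin2, Nectin3 and Afdn stand for the first 3.

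Named genes followed a rule fixed beforehand: Ptbp1, Ptbp2 and Ptbp3; the 8 largest rises and 8 largest falls past the threshold with an FPKM of at least 1 in the higher group and above 0 in both, without predicted genes; and from each list the 3 members past the threshold with the largest change, or, where fewer passed, the tested member with the highest mean FPKM as well. This gave 45 genes, a few of which are not reported here. All other genes named were chosen after their values were seen. Gene positions are 1-based and come from GENCODE release M21 on the same build; 98.6% of the deposited gene identifiers matched it with their version, and 99.98% of the matched genes lay inside the deposited locus.

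Near-identical copies of genes past the threshold and of all tested X and Y genes were sought with BLAST 2.17.0 by aligning each gene's longest transcript to all transcripts of the annotation, at 95% identity over 80% of its length, leaving out genes that overlap at the same locus. Calls per chromosome were compared with two-sided Fisher's exact tests against all other tested genes, with Benjamini-Hochberg adjustment over 42 tests. Windows of 5 Mb were scanned for calls and compared with 1000 random placements of the calls among tested autosomal genes; after the data were seen, the scan was repeated with the normal p from the statistic. For the beta-defensins, each member of a random set was drawn from the 200 genes nearest in the length of the longest transcript, without genes past the threshold. A comparison of the summed FPKM of the chromosome 4 region, set beforehand, was dropped as uninformative, since the lower genes held 281.1 of its 1880 FPKM in control and their full loss would not have reached the bound set against it.

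The weight of a fragment was read from genes with 1 transcript of a single exon of 1500 to 6000 bp, as FPKM multiplied by the length minus a deduction for fragment length, fitted at 260 bp in control and 264 bp in Ptbp1_cKO. Of the values small enough to hold 1 or 2 fragments, 99.5% of 430 in control and 100.0% of 428 in Ptbp1_cKO lay within 1% of a sum of 1 or 2 of 3 steps, against 20.3% and 20.4% of uniformly drawn values. A count of 3 fragments in one library corresponded to at most 0.0151 FPKM in control and 0.0154 FPKM in Ptbp1_cKO at an effective length of 1 kb. These figures cover counting error only.

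The p from the statistic, the list percentile, the window scan and the fragment steps were tested on simulated data. Fisher's exact tests and the length-matched sets were not. For the p from the statistic, 200 of 200 genes shifted by 6 units among 22048 were recovered, with 8 unshifted genes called. The simulated statistic was normal by design, so this checks the adjustment and not whether the deposited statistic is normal. Of 200 random lists of 25 genes, 4% fell outside the 2.5th to 97.5th percentile, and 100% lay above it after 0.2 had been added to their members. The scan found 50 of 50 planted windows. Each was planted with more calls than the densest window of the data held, so this does not show how well smaller clusters are found. The steps of 2500 simulated genes were recovered within 1e-05%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the q threshold, a fold threshold, an FPKM filter, the adjustment, the pseudocount, centring on the median gene and adjustment over each list; after the data were seen, a normal p from the statistic and counts without near-identical copies or sex-linked genes were added.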

Results

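Polyadenylated RNA from whole testes of mice aged 35 days was sequenced in 6 libraries. The 3 control libraries came from mice with floxed Ptbp1 alleles and no Cre, and the 3 Ptbp1_cKO libraries from floxed mice that also carried Amh-Cre, a recombinase expressed in Sertoli cells, the somatic cells that surround and nourish the germ cells. PTBP1 is an RNA-binding protein that controls alternative splicing, and the study addressed its role in Sertoli cells and their actin cytoskeleton. The labels give the strain as mixed and do not say whether each library came from a separate animal. The test results therefore speak for these libraries only. How Cuffdiff modelled the spread between them is not known, so a p-value need not reflect the spread of that gene. The authors' deposited table gives 1 FPKM value per group for each of 55331 genes, with Cuffdiff's test for 22048 of them, and no spread between libraries. FPKM values are therefore printed as the authors' group values, without SD.

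Low FPKM values moved in discrete steps from which the weight of 1 fragment could be read. In control the steps corresponded to 0.00384, 0.00457 and 0.00503 FPKM per fragment at an effective length of 1 kb, and in Ptbp1_cKO to 0.00463, 0.00500 and 0.00512 FPKM. If each group value is the mean of 3 libraries, these weights stand for 86900000, 72900000 and 66300000 fragments in the control libraries and 72000000, 66700000 and 65100000 in the Ptbp1_cKO libraries, on the scale on which Cuffdiff had normalised them. A gene with an effective length of 1 kb at 1 FPKM thus rested on about 226 fragments over the control group and 204 over the Ptbp1_cKO group. Which weight belongs to which replicate is not known.

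The targeted gene was reported first. Ptbp1 (ENSMUSG00000006498.16, chromosome 10, 79854427 to 79864771, mm10) had an FPKM of 49.97 in control and 46.66 in Ptbp1_cKO, a log2 fold change of -0.10 with q = 0.999 in the authors' deposited table. Its paralog Ptbp2, which is abundant in germ cells, stood at 157.1 and 151.7 FPKM, and Ptbp3 at 8.56 and 8.33 FPKM, both with q = 0.999 in the authors' deposited table. Whole testis holds many cells other than Sertoli cells, and a gene-level value does not separate a deleted exon from the rest of the transcript, so the Ptbp1 level does not check the labels here.

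The comparison of Ptbp1_cKO with control asks which transcripts of the testis differ between floxed mice with and without Amh-Cre. No group carried Amh-Cre without floxed Ptbp1, so an effect of the deletion cannot be told apart from an effect of the transgene. Genes past the threshold included genes of secreted proteins that rose from very low levels, such as Crisp1, and zinc-finger genes of chromosome 4 that fell to very low levels, such as Zfp990. Testicular marker genes that rose did so by far less, with Clu of Sertoli cells and Insl3 of Leydig cells each at 1.40 times the control FPKM. Of the 155 genes that fell, 76 lay on the X or Y chromosome, among them Sly and Cylc1, both expressed in spermatids. At q under 0.05 in the authors' deposited table, 101 genes were higher and 155 lower in Ptbp1_cKO, while 1979 of the 22048 tested genes had an unadjusted p under 0.05. Most changes were modest, with a median log2 fold change of 0.68 among the higher and -0.66 among the lower genes, and the 15793 tested genes with an FPKM of at least 1 in a group had a median of -0.005. The counts depended strongly on how the p-value was obtained. Computed from the deposited test statistic under a normal distribution, it left 9 higher and 10 lower genes past the threshold. Of these 19, 16 were among the 256 of the deposited test. The deposited calls did not follow the size of that statistic. Tma7-ps, at a statistic of -4.69, had q = 0.981 and Clu, at 2.63, had q = 0.00848 in the authors' deposited table. Whether a normal distribution is valid for the statistic is not known, so the lower counts do not decide how firm the deposited calls are.

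**Figure D1:**
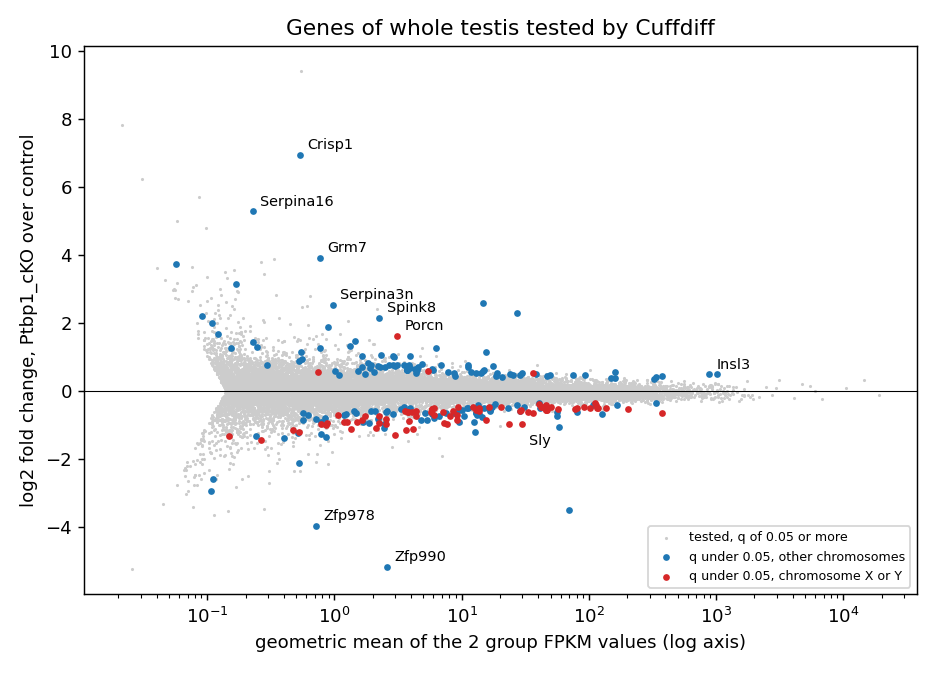
Log2 fold change of Ptbp1_cKO over control (vertical axis) against the geometric mean of both group FPKM values (horizontal log axis) for each tested gene above 0 in both groups, with genes at q under 0.05 in blue, or in red when on chromosome X or Y. Crisp1 lies highest among the coloured points at a log2 fold change of 6.94, Zfp990 lowest at -5.18, and most red points lie below 0.

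Among the genes with the largest rises, Crisp1 (ENSMUSG00000025431.4, chromosome 17, 40293758 to 40319207), which encodes a secreted protein of the epididymis, went from 0.0482 to 5.90 FPKM. Serpina16 (chromosome 12, 103668808 to 103676139) went from 0.0369 to 1.42 FPKM. Serpina3n, a serine protease inhibitor of the same chromosome (104406729 to 104414329), went from 0.402 to 2.32 FPKM. Grm7 (chromosome 6, 110645581 to 111567230), a metabotropic glutamate receptor, rose from 0.198 to 2.97 FPKM and Spink8 from 1.07 to 4.75 FPKM. Porcn, an acyltransferase that modifies Wnt proteins, rose from 1.78 to 5.43 FPKM, and the transcription factor Tbx3 rose 2.38-fold. These 7 genes had q = 0.00848 in the authors' deposited table, the value shared by the 130 genes at its smallest p of 5e-05. A further 4 genes past the threshold were listed at 0 in control, namely Ltf, Defb26, Defb28 and Spink10, at 1.10, 0.823, 0.539 and 0.295 FPKM in Ptbp1_cKO. Crisp1 belongs to the list of epididymis markers, and beta-defensins such as Defb26 and Defb28 are also known from the epididymis, a tissue adjoining the testis.

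Of the 8 falls named, the largest were in zinc-finger genes at the distal end of chromosome 4, where Zfp990 (ENSMUSG00000078503.9, 145510759 to 145539188) went from 15.6 to 0.431 FPKM and Zfp978 (147361303 to 147391004) from 2.86 to 0.181 FPKM. Nearby, Zfp984 (147753974 to 147809788) fell less, from 2.32 to 1.22 FPKM. Each had q = 0.00848 in the authors' deposited table; Zfp978 shares near-identical sequence with 3 other genes, so its value is uncertain. The complement factor gene Cfd fell from 1.23 to 0.501 FPKM with q = 0.0202 in the authors' deposited table, and the water channel Aqp5 from 1.08 to 0.565 FPKM. The other falls named were sex-linked: Sly of the Y chromosome fell from 42.0 to 21.3 FPKM, the X-linked homeobox gene Rhox11 from 10.2 to 5.23 FPKM, and the X-linked Tgif2lx1 from 2.24 to 1.23 FPKM. Sly has 85 near-identical genes in the annotation and Tgif2lx1 has 1, so reads are shared among copies and both values are uncertain.

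Lower calls were concentrated on the sex chromosomes, a comparison made after the data were seen. On the X chromosome 55 of 892 tested genes were lower, or 6.17% against 0.473% of genes elsewhere (two-sided Fisher's exact test, adjusted p = 1.81e-35 over 42 tests), and on the Y chromosome 21 of 205, or 10.2% against 0.614% (Fisher's exact test, adjusted p = 2.58e-17). Higher calls showed no such excess, with 4 on X and 0 on Y. Genes are not independent replicates, so these p-values are descriptive. The median log2 fold change of genes with an FPKM of at least 1 was -0.13 on X (586 genes), -0.66 on Y (73 genes) and -0.002 on the autosomes (15123 genes). X-linked genes that fell in the authors' deposited table included Cylc1, a cytoskeletal protein of the sperm head (245.1 to 167.4 FPKM), Tex13a (93.6 to 64.5 FPKM), Zcchc13 (120.5 to 85.2 FPKM), Cypt2 (59.5 to 42.2 FPKM) and the histone H2al3 (132.18 to 97.53 FPKM). Of the 20 Y-linked lower genes searched, 19 had a near-identical copy, and their single values are uncertain. With the normal p from the statistic, 0 X-linked and 2 Y-linked genes were lower. Whether a normal distribution is valid for that statistic is not known, so these counts do not decide how firm the sex-linked calls are.

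Cell type markers were compared through 12 lists. Over these and the 7 process lists, 11 members passed the deposited threshold, and of these Crisp1 alone also passed with the normal p from the statistic. Among 25 Sertoli cell markers, Clu (chromosome 14, 65968483 to 65981547), a secreted chaperone, rose from 853.6 to 1199 FPKM with q = 0.00848 in the authors' deposited table, and none passed the threshold in the other direction. Ctsl stood at 396.6 and 322.5 FPKM (q = 0.318 in the authors' deposited table). Adjusted over the list alone, 3 markers were higher, adding Sox9 (5.33 and 6.93 FPKM) and the inhibin subunit Inha (37.4 and 46.8 FPKM). The FPKM was higher in Ptbp1_cKO for 22 of the 25, and the list's median difference of log2(FPKM + 1) was 0.11, above 99.9% of 10000 random lists matched on expression. The other lists of somatic cells also lay high among random lists, so the rise was not particular to Sertoli cells. Percentiles were 100 for stroma and matrix, 100 for leukocytes, 99.7 for myoid, 99.55 for blood and 97.9 for endothelial cells. A different share of these cells cannot be told apart from a change within them. Insl3 (chromosome 8, 71689214 to 71690575), a peptide hormone of Leydig cells, rose from 749.6 to 1049 FPKM with q = 0.00848 in the authors' deposited table; over the list alone 3 of 17 Leydig cell markers were higher, and the median was 0.10 (percentile 99.8). Leydig cell markers went both ways, with a higher FPKM for 11 and a lower one for 6, among them Star, Cyp17a1, Fdx1 and Cyp11a1. Star, which regulates steroid synthesis, stood at 85.5 and 63.6 FPKM (unadjusted p = 0.0149, q = 0.321 in the authors' deposited table). In the stroma and matrix list all 12 members had a higher FPKM in Ptbp1_cKO. Col1a1 (1.70 to 2.49 FPKM) and the proteoglycan Dcn (24.8 to 35.4 FPKM) rose past the threshold of the authors' deposited table, with Sparc at 132.0 and 163.5 FPKM (q = 0.103). Adjusted over the list alone 5 passed as higher, and the median was 0.28. The complement gene C1qb (11.8 to 16.8 FPKM) and the Fc receptor chain Fcer1g (3.74 to 6.39 FPKM) rose among 21 leukocyte markers, with Aif1, which germ cells also express, at 366.3 and 353.8 FPKM in the authors' deposited table. Over that list alone 5 were higher and 1 lower, with a median of 0.23. No peritubular myoid (0 of 11, median 0.16), endothelial (0 of 11, median 0.12) or blood cell marker (0 of 5 tested, median 0.27) passed the threshold over all genes; the counts at an unadjusted p under 0.05 were 0, 1 and 3. Adjusted over the list alone these counts were 0 and 0 for myoid and endothelial cells, and 2 higher and 1 lower for blood cells. The most abundant members were Actg2 at 136.5 and 154.4 FPKM, Egfl7 at 3.86 and 4.57 FPKM and Hbb-bs at 5.85 and 8.40 FPKM.

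Medians of the germ cell lists lay on both sides of 0. In the spermatogonial list, the receptor Kit (3.001 to 4.574 FPKM) and the ubiquitin hydrolase Uchl1 (40.3 to 54.7 FPKM) rose with q = 0.00848 and q = 0.0420 in the authors' deposited table, Dmrtb1 stood at 1284 and 1191 FPKM, and the list median was 0.01 (percentile 54.5); adjusted over the list alone 3 of 19 were higher. None of the 26 spermatocyte markers passed Cuffdiff's threshold over all genes or adjusted over the list alone (1 had an unadjusted p under 0.05), with Syce1 at 308.2 and 281.4 FPKM and a median of -0.08 (percentile 11.02). None of the 20 round spermatid markers passed over all genes (3 had an unadjusted p under 0.05); adjusted over the list alone 1 was lower, Lyzl1 at 122.4 and 95.1 FPKM. Their median was -0.12 (percentile 5.87), and the most abundant, Tex33, stood at 994.5 and 942.1 FPKM. None of the 21 tested elongating spermatid markers passed either (3 had an unadjusted p under 0.05); adjusted over the list alone 2 were higher, the protamine Prm1 (13135 and 16362 FPKM) and Oaz3 (1589 and 1919 FPKM). That list had a median of 0.14, above all 10000 random lists (percentile 100), while the transition protein Tnp1 stood at 19773 and 18244 FPKM. Of the 8 epididymis markers, 4 had under 0.1 FPKM in both groups and Crisp1 alone passed the threshold, over all genes and adjusted over the list alone, with a list median of 0.20 over 4 members.

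**Figure D2:**
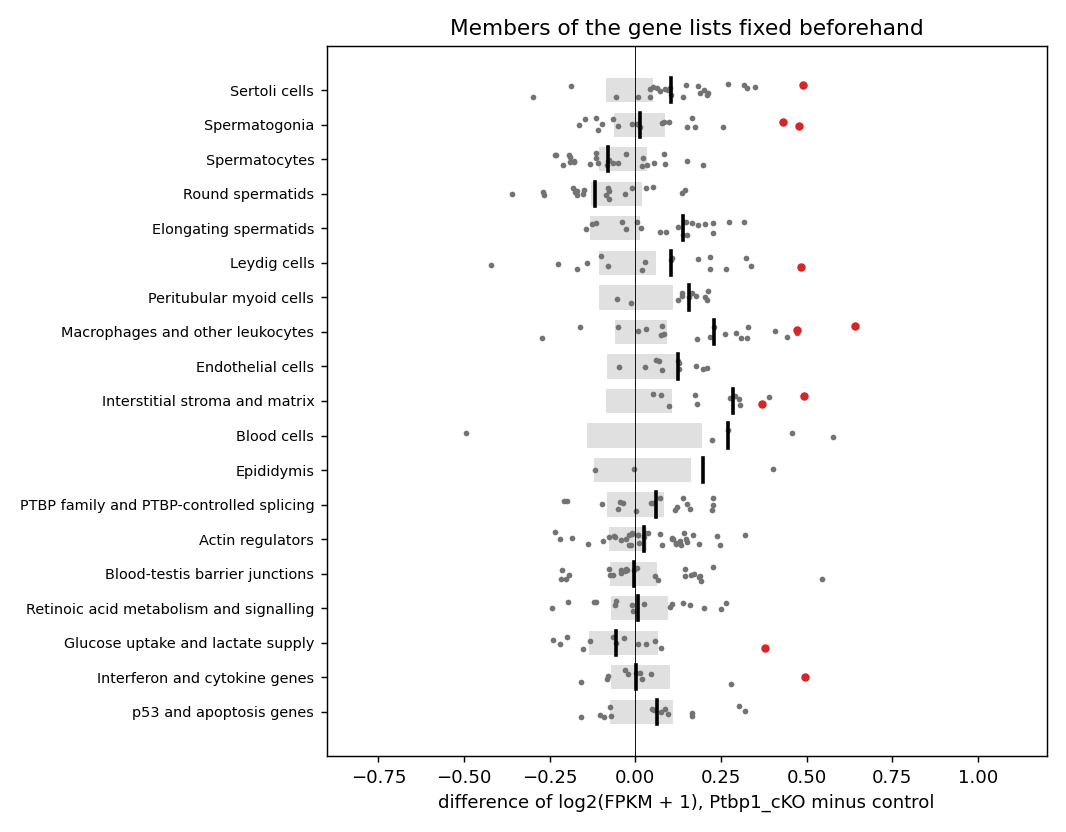
Difference of log2(FPKM + 1), Ptbp1_cKO minus control (horizontal axis), for each member of 19 gene lists, with red points at q under 0.05, black bars at list medians and grey bands over the central 95% of the medians of random lists; Crisp1 of the epididymis list, at 2.72, lies beyond the axis. Medians of 9 lists lie above their band, the largest being 0.28 for interstitial stroma and matrix, and no median lies below its band.

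The processes closest to the study's question gave few calls. Whole testis holds many cells other than Sertoli cells, so a change confined to Sertoli cells can be diluted. An absence of calls therefore does not show that these processes were unchanged there. None of 38 actin regulators passed Cuffdiff's threshold over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05; Actb stood at 281.7 and 332.4 FPKM with q = 0.622 in the authors' deposited table, and the list median was 0.03 (percentile 95.6). None of 24 tested junction genes of the blood-testis barrier passed, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, with Nectin3 at 303.6 and 295.0 FPKM and a median of -0.005 (percentile 53.6). Among 18 genes of the PTBP family and of transcripts known to be spliced under PTBP control, 0 passed either way by Cuffdiff's test and 1 had an unadjusted p under 0.05; Matr3 was at 253.7 and 219.5 FPKM and the median was 0.06 (percentile 93.0). Gene-level values do not show exon use, so they leave splicing unmeasured. Of 13 genes of glucose uptake and lactate supply, the lactate dehydrogenase subunit Ldhb rose from 130.6 to 170.0 FPKM (q = 0.0248 in the authors' deposited table), over all genes and over the list alone, whereas the germ cell subunit Ldhc stood at 2333 and 2030 FPKM; the median was -0.06. One of 11 tested interferon and cytokine genes, Oasl2, rose from 1.95 to 3.16 FPKM (q = 0.0359 in the authors' deposited table) over all genes and over the list alone, and the list median was 0.002. None of 16 retinoic acid genes (median 0.01, Aldh1a1 at 124.1 and 133.8 FPKM) and none of 14 p53 and apoptosis genes (median 0.06, Mdm2 at 94.6 and 84.7 FPKM) passed Cuffdiff's threshold over all genes or adjusted over the list alone, and 2 of each had an unadjusted p under 0.05.

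Calls also clustered by position, a feature examined after the data were seen. On chromosome 4 between 140872693 and 147753974 (mm10), 5 genes were higher and 9 lower among 88 tested. Besides the zinc-finger genes named above, the non-coding Gm13165, which overlaps Zfp600, fell from 235.9 to 20.6 FPKM in the authors' deposited table, while Fam131c (2.21 to 3.75 FPKM), Pdpn (3.01 to 4.57 FPKM) and the retinal reductase Dhrs3 (2.40 to 4.05 FPKM) rose. The autosomal window of 5 Mb with the most calls, from 141368220 to 146368219 on this chromosome, held 10 calls among 50 tested genes, and the largest window in 1000 random placements of the 176 autosomal calls held 7. With the normal p from the statistic, 4 genes of the region passed, all of them lower, and 2 of these lay in that window. The scan repeated with the normal p found its largest window, of 4 calls, again on this chromosome (from 145510759), against at most 3 in 1000 random placements. Within 2 Mb of Ptbp1 on chromosome 10, 4 of 152 tested genes were higher, namely Midn, Rexo1, Gipc3 and Tle5, and Cfd was lower. Thus 3.29% were called there against 1.16% of all tested genes (two-sided Fisher's exact test, unadjusted p = 0.0325). None of these called genes passed with the normal p from the statistic.

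**Figure D3:**
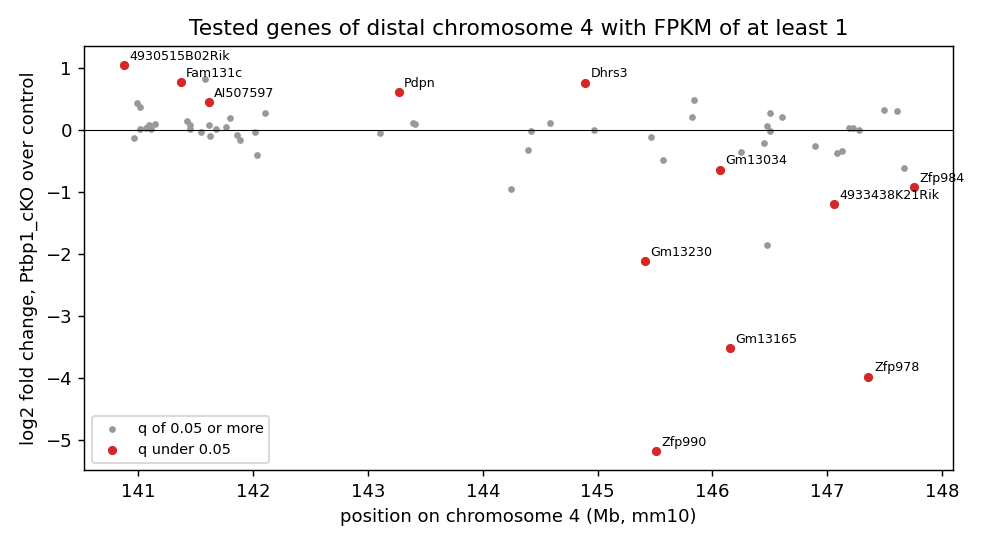
Log2 fold change of Ptbp1_cKO over control (vertical axis) by gene position on chromosome 4 in Mb, mm10 (horizontal axis), for tested genes of the region with an FPKM of at least 1 in a group, with genes at q under 0.05 in red and named. Zfp990, Zfp978 and Gm13165 lie at log2 fold changes of -5.18, -3.98 and -3.52, while Dhrs3, Pdpn, AI507597, Fam131c and 4930515B02Rik lie above 0.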

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

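Of the tests below, the search for near-identical copies of X-linked genes and the test of zinc-finger genes elsewhere were set before their results were seen; the others were chosen after the result was seen. The genes marked with too much data lay outside the test, and 5 of them had a value in Ptbp1_cKO and were listed at 0 in control: Pabpc1 at 1856 FPKM, Ermard at 7.65 FPKM, Gm3448 at 3.62 FPKM, Tcte3 at 1.80 FPKM and Gm3435 at 1.53 FPKM. The mitochondrial mt-Nd1, mt-Nd4 and mt-Nd4l were the other way round, at 5399, 1278 and 1.43 FPKM in control and listed at 0 in Ptbp1_cKO. No direction was read from these values.

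The first pattern is the excess of X-linked and Y-linked genes among those lower in Ptbp1_cKO. Shared reads are argued against as the whole cause on X, where 20.4% of the 54 lower genes searched had a near-identical copy (19.9% of all 866 tested X genes searched) and 6.20% of the 694 tested X genes without one were lower, against 0.377% of autosomal genes; among X genes with an FPKM of at least 1, however, the 75 with a copy had a median log2 fold change of -0.50 and the 497 without one -0.10. On Y, where 92.1% of tested genes have a copy, all 62 genes with a copy and an FPKM of at least 1 had a median of -0.72 (25th to 75th percentile -0.97 to -0.56) against -0.22 (-0.33 to -0.16) for the 9 without. A different copy number in the Ptbp1_cKO group thus remains a candidate explanation for the Y part, although the genes with and without copies may also differ in the cells that express them. Sharing of reads among the Y copies alone would lower some copies and raise others. Of the 73 Y genes with an FPKM of at least 1, however, 94.5% were lower, which argues against such sharing as the whole cause for these genes. A smaller share of round spermatids cannot be told apart from a change within them. The autosomal round spermatid list had a median of -0.12 against -0.35 for 42 X-linked spermatid genes. However, 5 of the list's 20 members lay at or below -0.176, the bound set, and several are also expressed in spermatocytes. The X-linked families were listed after the data were seen, and 13 of their genes are themselves lower calls. Their median, and the bound taken from it, are thus drawn towards the pattern. An effect of the deletion on spermatids stays open and untested.

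The second pattern is the cluster of calls on distal chromosome 4. An effect on zinc-finger genes as a class is argued against by the 285 Zfp genes elsewhere, whose median log2 fold change was -0.0113 (25th to 75th percentile -0.12 to 0.12). A shift of reads between near-identical genes is argued against as the whole cause, since 14.3% of the 14 calls of the region had a near-identical copy (22.2% of the 9 lower calls). Reads shared over shorter or less similar stretches were not tested. A background haplotype that differs between the groups, whose labels give a mixed strain, cannot be told apart from an effect of the deletion or of the Amh-Cre transgene on this region: the window held 10 calls, as any local cause would give, and no genotype was examined.

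The third pattern is the appearance of epididymal transcripts in Ptbp1_cKO, namely Crisp1, Ltf, Spink10, Wfdc16 and beta-defensins. Leaving out Defb26 and Defb28, which passed the threshold and drew attention to the family, 9 of 14 beta-defensin genes with under 0.1 FPKM in control and any signal reached 0.1 FPKM in Ptbp1_cKO, against at most 8 in 10000 random sets of such protein-coding genes matched on transcript length, so some epididymal tissue in a Ptbp1_cKO library is a candidate source. As members of a family, the 14 are not independent, so random sets of unrelated genes can understate the spread. None of the 9 passed, 5 were not tested, and 0.1 FPKM is about 3.4 fragments at the median length of the 14, 431 bp, while 0 of the 12 at 0.1 FPKM or more in control passed the threshold (Defb41 stood at 0.349 and 0.245 FPKM and Defb48 at 0.253 and 0.192 FPKM). Tissue of the whole epididymis is argued against, since Gpx5, Lcn5, Lcn8 and Lcn9 of its proximal part reached at most 0.0349 FPKM beside 5.90 FPKM for Crisp1. Within the list fixed beforehand, Adam7 stood at 0.00142 and 0.323 FPKM with q = 0.999 in the authors' deposited table, and Rnase10 and Cst11 at 1.98 and 1.98 FPKM and at 0.287 and 0.185 FPKM; induction of these genes in the testis after the deletion stays open, since values per library were not used.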

How the results depend on the processing

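No paired analysis was possible because the values used carry no replicate number; for the same reason leaving out a replicate, a replicate block, per-library pseudocounts, the count-based tools and other splits of the samples were not run. The normal p from the test statistic and the counts without copies or sex-linked genes were chosen after seeing the data. Against 101 higher and 155 lower genes, a q under 0.01 gave 50 and 80, and the normal p gave 9 and 10. A log2 fold change of at least 1 (genes listed at 0 in a group included) gave 31 and 27. Fewer genes pass at the stricter q and at the fold threshold by construction. Whether the normal p is valid for the deposited statistic is not known, and the cause of its lower counts was not tested. Leaving out genes with a near-identical copy gave 99 lower genes and leaving out X and Y gave 79, by construction, while the higher genes numbered 101 and 97. An FPKM filter with new adjustment gave 100 and 155, and adjustment computed again gave 101 and 155. Lower genes on X, 55 in the main test, numbered 25 at q under 0.01, 3 at a log2 fold change of at least 1, 44 without those found to have a copy and 0 with the normal p. Those on Y, 21 in the main test, numbered 10, 7, 2 and 2. Genes not searched for copies stayed in the counts without copies: 152 of the 155 lower genes were searched, 54 of the 55 on X and 20 of the 21 on Y. For the named genes, centring moved each fold by 0.005 and log2(FPKM + 1) cannot change a sign, so these settings say nothing of their stability. Of 76 alternative list medians, 68 moved by less than 0.5 times the width of the central 95% of random list medians. The others were spermatogonia (0.11 with no pseudocount, from 0.01), endothelial cells (0.24 with none, from 0.12), blood cells (0.47 with a pseudocount of 0.1 and 0.51 with none, from 0.27), epididymis (1.03 with 0.1, 3.47 with none and 1.36 over members at 1 FPKM or more, from 0.20) and interferon genes (0.16 over members at 1 FPKM or more, from 0.002). By ratio, further medians moved by over 1.5 times: Sertoli cells (0.17 with none, from 0.11), endothelial cells (0.22 with 0.1, from 0.12), PTBP targets (0.10 with none, from 0.06), and near-zero medians of spermatogonia, junctions, retinoic acid genes and interferon genes under other settings. The near-zero medians of 3 lists changed sign, those of junctions, retinoic acid genes and spermatogonia. Adjusted over the list alone, 9 of 38 counts moved by over 1.5 times. Depth limits low values: a transcript with an effective length of 1 kb at 0.1 FPKM rests on about 22.6 fragments over the control group and 20.4 over the Ptbp1_cKO group.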

Other observations

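Some autosomal genes that fell belong to a multicopy family of the testis, looked at after the data were seen. All 13 tested Speer genes, most of them on chromosome 5, had a lower FPKM in Ptbp1_cKO, and 3 fell past the threshold in the authors' deposited table, among them Speer4c from 18.74 to 10.98 FPKM. Speer4c has 5 near-identical genes and Speer4a, another of the 3, has 8, so reads are shared and both values are uncertain. Speer4e, the remaining one, has 0. As members of a family, the 13 are not independent. Chromosome 14 held 15 lower genes of 957 tested (1.57% against 0.664% elsewhere, Fisher's exact test, adjusted p = 0.0289 over 42 tests). Of these 15 genes, 9 had a near-identical copy, so that their single values are uncertain and they are not independent calls. The excess can therefore count the same event several times, and its p-value is descriptive. Whether it holds without the genes that have a copy was not tested. By Fisher's exact test, chromosomes 9 (0 of 1214, adjusted p = 0.00381), 3 (0 of 1079, adjusted p = 0.0105) and 11 (2 of 1527, adjusted p = 0.0182) held fewer than elsewhere. That comparison includes the many lower genes of X and Y. Outside chromosome 9, 0.744% of tested genes were lower, against 0.377% of all autosomal genes. Whether these 3 chromosomes held fewer lower genes than the other autosomes was not tested. Among the 79 autosomal lower genes, 26 had a near-identical copy.

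Further genes rose that no list holds. In the authors' deposited table, the glutathione peroxidase Gpx3 rose from 10.4 to 23.0 FPKM, the glutathione transferase Gstm1 from 131.4 to 193.1 FPKM, the complement inhibitor Serping1 from 13.7 to 22.7 FPKM and the matrix protein Prelp from 2.08 to 4.12 FPKM, while Pros1, an anticoagulant protein and ligand for phagocytic receptors, fell from 8.03 to 4.57 FPKM.

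Large ratios that missed the threshold were also looked at after the data were seen. The transcript 1700030L22Rik of chromosome 12 stood at 0.0208 and 14.1 FPKM with q = 0.661 in the authors' deposited table. Genes picked for such ratios included Cd52, which leukocytes also express, at 0.943 and 5.03 FPKM (q = 0.268), Rnase9 at 0.0186 and 0.514 FPKM (q = 0.289) and Pate1 at 0.00355 and 0.263 FPKM (q = 0.745) in the authors' deposited table. They are known from the epididymis, but none passed the threshold, and genes picked for their ratio say nothing of how others behaved: Cst11 was lower, at 0.287 and 0.185 FPKM, as were Defb41 at 0.349 and 0.245 FPKM and Defb48 at 0.253 and 0.192 FPKM, and Rnase10 stood at 1.98 FPKM in both groups.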
